A study of Mus musculus with 6 samples.

How the data were processed

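The measurements are microarray signals of 6 RNA samples, 3 from Eomes+ and 3 from Eomes- CD8 T cells sorted from treated tumours, grouped by the sample titles. The authors deposited log2 values in a table of 45101 probe sets, with values between 1.68 and 14.95. Transcriptome Analysis Console and MAS5 are named in the submitters' processing notes, without versions and without saying what each did, so the summary method behind the log2 values is not given in the sources used here. The scale was read from the values, since no header states it: powers of 2 of the highest value stay below the largest 16-bit scanner value of 65535. The arrays have nearly equal medians and percentiles, so a shift common to most genes of an array would have been removed before deposit. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols.

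Control probe sets (64) were left out of the tests. Of the other 45037, the platform annotation gives 1 gene symbol for 34945, several for 932 and lists none for 9160, and those with several or none were not named. Symbols were updated through the gene identifier in a RefSeq table of assembly GRCm38.p6, which held 34754 of the 34945. A probe set was kept if it lay above its array's 40th percentile on at least 3 of the 6 arrays (27766 probe sets, 23331 with 1 gene), and the brightest probe set stood for each gene, giving 12571 genes. No probe set below this filter was tested, and differences near it are compressed by background signal. No genome coordinates are printed because no build is stated for the table.

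Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 27 gene lists, the filter, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members (25) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. The 3' to 5' ratio of the Gapdh and Actb control probe sets was compared with an exact permutation test, in which 3 against 3 cannot go below p = 0.1. Named genes were Eomes, the 10 largest differences in each direction among genes past the threshold with groups that do not overlap, with free places filled from genes at an unadjusted p under 0.05 (all of those named here, none of which passed), up to 4 members of smallest p per list, and a fixed set of T cell genes whatever their values. The sex-linked genes of the closing section were chosen after their values were seen.

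Replicate numbers were not used as a block in the main fit, because no stated method uses one and no label ties a number to an experiment. A check of whether the numbers pair the samples also missed its rule, narrowly and for replicate 2 only (correlation 0.0989). Over spiked-in control probe sets, however, each array correlated best with the array of its own number. If the numbers do pair the samples, the fit without a block may overstate the spread. Alternatives were a replicate block, other pseudocounts, quantile normalization, median centring, no filter or a stricter filter at the 60th percentile, other choices of probe set, other variance models, array weights and samples left out. A covariate for RNA of other cells and the block combined with other choices were added after seeing the data.

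The fits were tested on simulated data for 12571 genes of which 200 were changed. The simulated values had the real means, noise of the real size within a replicate, and replicate differences with a sign drawn at random per gene. Without a replicate block, 0% of genes changed by 0.5 log2 were recovered, 2% at 1 log2, 24% at 2 log2 and 82% at 3 log2, with 0 false calls. With the block the shares were 10%, 42%, 98% and 100%, with 12 false calls among 137. The simulation gave arrays of 1 number a shared shift, so it favours the block by construction. A simulated list of 20 genes shifted by 0.6 log2 was called, and 0 of 24 unshifted lists were. These lists held genes drawn at random, without the correlation between members estimated for the real lists (up to 0.969). They therefore do not show how often camera calls a correlated list falsely.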

Results

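CD8 T cells were sorted from MCA-205 tumours, a transplanted mouse fibrosarcoma, grown in male mice that carry a GFP reporter of Eomes, a T-box transcription factor of effector and memory CD8 T cells. All mice had received an antibody to the costimulatory receptor OX40, 250 ug on days 12 and 16, and an antibody to the inhibitory receptor CTLA-4, 200 ug on days 12, 14 and 16, and tumours were taken on day 19. RNA of the GFP-positive (Eomes+) and GFP-negative (Eomes-) fractions was hybridised to microarrays, with 3 arrays of each fraction. The comparison asks how CD8 T cells with and without Eomes differ in the same treated tumours, and untreated mice were not analysed here. The median log2 signal of the 6 arrays lay between 6.35 and 6.42, and the number of arrays limits the precision of every value given. The labels speak of 3 independent experiments but tie no array to an animal, so p-values measure the spread between these samples.

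Eomes itself was 8.90-fold higher in the fraction sorted as Eomes+, at 9.54 ± 1.04 log2 (SD, n = 3) against 6.39 ± 0.83 in Eomes-, for the brighter of its probe sets. Every Eomes+ array lay above every Eomes- array. The other Eomes probe set was 7.28-fold higher. In the unweighted fit with the fraction as its only term, Eomes did not pass the test over all genes (log2 difference 3.15, SE 0.64; limma adjusted p = 1.00, unadjusted p = 0.00205), although the cells had been sorted on its reporter.

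Among the genes with the largest differences were an integrin gene, a granzyme gene and receptor genes of the NK type. Itgae, the CD103 integrin chain that binds epithelial E-cadherin, was 5.37-fold lower in Eomes+ cells, at 7.77 ± 0.52 log2 against 10.19 ± 0.50 (SD, n = 3 each). Upk1a, a uroplakin gene, was 8.60-fold lower, and the C-type lectin receptor gene Klrb1a was 4.46-fold lower. On the other side, the phosphodiesterase gene Pde2a was 6.54-fold higher, the aquaporin gene Aqp9 5.60-fold higher, the cannabinoid receptor gene Cnr2 4.65-fold higher and the Ly49 receptor gene Klra7 3.96-fold higher. The Klra7 probe set is of a kind open to cross-hybridisation, so its signal may include related genes, although the other Klra7 probe set differed in the same direction. Aqp9 and Cnr2 lay below the filter level, each array's 40th percentile, on 2 of 3 Eomes- arrays, and Upk1a on 1 of 3 Eomes+ arrays, so the sizes of these differences are uncertain.

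None of these genes passed correction in this fit. Of 12571 genes tested, limma called 0 at an adjusted p under 0.05, with 409 at an unadjusted p under 0.05 where chance alone gives 629. The count of 0 depends on the fit: over all the settings tried, some of them added after seeing the data, it ranged from 0 to 253 genes, and Eomes passed in 4 of them. The groups did not overlap for 969 genes, 7.71% of those tested against a chance share of 10%. Counts below chance do not show that the fractions are alike, since differences between arrays of the same fraction enter the spread of this fit. Without correction, 122 genes had an unadjusted p under 0.05 and at least a 2-fold difference, 52 higher and 70 lower in Eomes+ cells. That uncorrected number was 202 without Eomes+ replicate 1 and 334 without Eomes- replicate 3. The other genes of largest difference with separate groups were, on the higher side, Dmrta1 (2.29 log2), Cd163l1 (1.97), Tmem86b, Zfp365 and 5830411N06Rik. The last 3 lay below the filter level on all 3 Eomes- arrays, so no size is given for them, and Dmrta1 lay below it on 1. On the lower side they were Sema4c (-2.21 log2), Igsf5 (-1.92), Slc17a6 (-1.89), Kcna4 (-1.86), Gm36723 (-1.82), Gzme (-1.81) and Ccdc184 (-1.79). Of these, Igsf5 and Kcna4 lay below the filter level on 2 of 3 Eomes+ arrays and Sema4c and Slc17a6 on 1, so their sizes are uncertain.

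**Figure D1:**
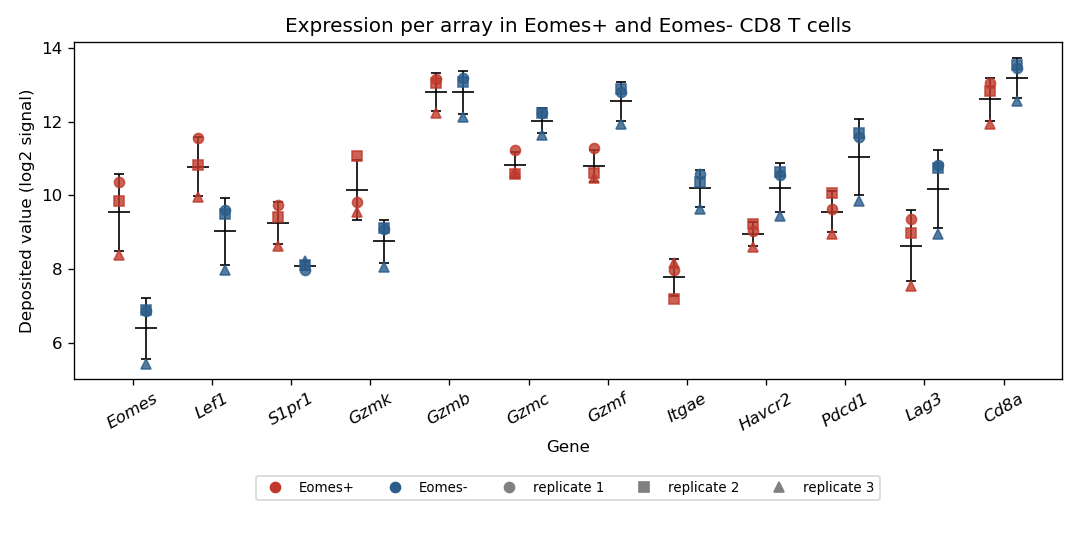
Deposited log2 signal (vertical axis) of 12 named genes (horizontal axis) in the 3 Eomes+ (red) and 3 Eomes- (blue) arrays, with the marker shape giving the replicate number and black bars the mean ± SD. Eomes lay at 9.54 against 6.39 and Itgae at 7.77 against 10.19, whereas Gzmb lay at 12.82 and 12.80.

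Genes of inhibitory receptors and exhaustion were lower as a group in Eomes+ cells. Of 22 members, 18 were tested and 13 had a lower mean, with a list median of -0.55 log2. Pdcd1, which encodes PD-1, differed by -1.48 log2 (SE 0.55), Havcr2, which encodes TIM-3, by -1.26 (SE 0.37), Lag3 by -1.55 (SE 0.67), Ctla4 by -0.85 (SE 0.43) and the transcription factor gene Tox by -0.61 (SE 0.54). Over all genes 0 members passed, and adjusted over the list alone 0 passed. The list passed camera with a preset correlation (adjusted p = 0.00116) and not otherwise (adjusted p = 0.844 with an estimated correlation). The call was also lost without Eomes+ replicate 3 (median -0.35 log2, adjusted p = 0.123), and the median was -0.84 log2 without Eomes- replicate 3. Without both arrays of number 1, 2 or 3 the call was kept (camera adjusted p = 0.00798, 0.033 and 1.38e-07).

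Genes of stem-like, naive and memory T cells were higher as a group in Eomes+ cells. The list had 18 tested members of 21, of which 13 had a higher mean, and its median was 0.59 log2. Lef1, a transcription factor of naive and memory T cells, was 1.76 log2 higher (SE 0.57), S1pr1, the receptor for egress from tissue, 1.17 (SE 0.33), Klf2 0.62 (SE 0.35) and Slamf6 1.01 (SE 0.57), although both other Slamf6 probe sets differed in the opposite direction. Il7r differed by -0.36 log2 (SE 0.53), and Tcf7 was not tested here. No member passed over all genes or adjusted over the list alone (0 and 0). The list passed camera (adjusted p = 0.000375; adjusted p = 0.713 with an estimated correlation), and it passed with each array left out in turn. The Gapdh 3' to 5' ratio, a sign of RNA quality, was also higher on all 3 Eomes+ arrays, at 1.74 ± 0.17 log2 against 1.24 ± 0.26 (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest this design allows). For the mean of Gapdh and Actb the ratio was 0.93 ± 0.08 against 0.65 ± 0.11 (exact permutation p = 0.1).

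Granzyme and cytotoxicity genes had a lower mean in Eomes+ cells in 15 of 23 tested members. The cluster members Gzmf (-1.76 log2, SE 0.33), Gzmc (-1.22, SE 0.25) and Gzmd (-1.66, SE 0.37) fell in Eomes+ cells when adjusted over the list alone (3 of 23 tested members; limma adjusted p = 0.0271, 0.0271 and 0.0273), and 0 passed over all genes. Gzmk was 1.40 log2 higher (SE 0.49), and Gzmb, the main cytotoxic granzyme of effector cells, differed by 0.02 log2 (SE 0.36), a difference that turned negative under several settings. The list of granzymes and cytotoxic machinery had a median of -0.31 log2 and passed camera (adjusted p = 0.0275; adjusted p = 0.844 with an estimated correlation). Its call was lost without Eomes+ replicate 3 (median -0.00027 log2, adjusted p = 0.776), Eomes- replicate 1 (-0.17, 0.297) or Eomes- replicate 2 (-0.08, 0.302), and the median was -0.51 log2 without Eomes+ replicate 1 and -0.61 without Eomes- replicate 3. Without both arrays of number 1, 2 or 3 the median was -0.37, -0.23 and -0.29 log2 (camera adjusted p = 0.0114, 0.279 and 0.000112). With the level of tumour and macrophage markers as a covariate the median was -0.12 log2 (adjusted p = 0.0628). Gzmd, Gzme and Gzmf are close relatives, and their probe sets can share signal.

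Tissue residency, costimulatory receptor and effector cytokine genes were lower as groups in Eomes+ cells. Of 16 tested residency genes 13 had a lower mean, and Itgae (-2.42 log2, SE 0.38) and Litaf (-0.55, SE 0.13) fell when adjusted over the list alone (limma adjusted p = 0.00748 and 0.0388), with 0 over all genes. Of 17 tested costimulatory receptor and ligand genes 15 had a lower mean, among them Tnfrsf4, which encodes OX40, one target of the treatment (-1.24 log2, SE 0.54), and Slamf1 (-1.77, SE 0.61), with 0 passing over all genes and 0 adjusted over the list alone. Of 9 tested cytokine genes 8 had a lower mean, among them Il2 (-2.12 log2, SE 0.89, below the filter level on 1 Eomes+ array) and Ifng (-1.02, SE 0.63), again with 0 and 0 passing. List medians were -0.34, -0.37 and -0.37 log2, and camera gave adjusted p = 0.00446, 0.00475 and 0.0301 in that order (adjusted p = 0.844, 0.844 and 0.713 with an estimated correlation). All 3 calls were lost without Eomes+ replicate 3 (adjusted p = 0.574, 0.859 and 0.236), where the medians were -0.08, 0.01 and -0.28 log2, so the costimulatory median turned sign. They were lost without Eomes- replicate 2 (0.0785, 0.359 and 0.163; medians -0.14, -0.16 and -0.29) and without Eomes- replicate 1 (0.199, 0.491 and 0.0599; medians -0.22, -0.03 and -0.38), and the cytokine call was lost without Eomes+ replicate 1 (0.0941). Without Eomes- replicate 3 the medians were larger, at -0.65, -0.71 and -0.85 log2. Without Eomes+ replicate 1 they were -0.55, -0.56 and -0.37, and without Eomes+ replicate 2 -0.37, -0.59 and -0.76. With both arrays of replicate 3 left out all 3 calls were kept (medians -0.37, -0.23 and -0.73 log2; camera adjusted p = 9.22e-05, 0.000109 and 0.00469). With both arrays of replicate 1 left out the residency call alone was kept (0.00634, 0.0528 and 0.0583). With both of replicate 2 left out the cytokine call alone was kept (0.066, 0.0819 and 0.0216). With the level of tumour and macrophage markers as a covariate the medians were -0.18, -0.19 and -0.33 log2 (adjusted p = 0.0405, 0.0335 and 0.0596).

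Interferon response genes were slightly higher in Eomes+ cells, with 27 of 32 tested members higher and a median of 0.16 log2. Ifit1 differed by 0.42 log2 (SE 0.19), and the immunoproteasome gene Psmb9 by -0.27 (SE 0.10). No member passed over all genes (0) or adjusted over the list alone (0). The list passed camera (adjusted p = 0.00217; adjusted p = 0.844 with an estimated correlation), and not without Eomes+ replicate 1 (0.0941) or Eomes- replicate 1 (0.203).

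Genes used as markers of CD4 and regulatory T cells were lower in Eomes+ cells in 9 of 9 tested members, with a median of -0.75 log2. Capg, an actin-capping protein gene (-0.77 log2, SE 0.17), and Cd40lg, the CD40 ligand gene (below the filter level on all 3 Eomes+ arrays, so no size is given), fell when adjusted over the list alone (limma adjusted p = 0.032 and 0.0355), with 0 over all genes. Cd4 itself differed by -0.24 log2 (SE 0.27) and Foxp3 by -0.34 (SE 0.27). The list passed camera (adjusted p = 2.69e-05; adjusted p = 0.198 with an estimated correlation). It passed with each array left out in turn, with medians down to -0.50 log2 without Eomes- replicate 2 and -0.52 without Eomes- replicate 1.

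**Figure D2:**
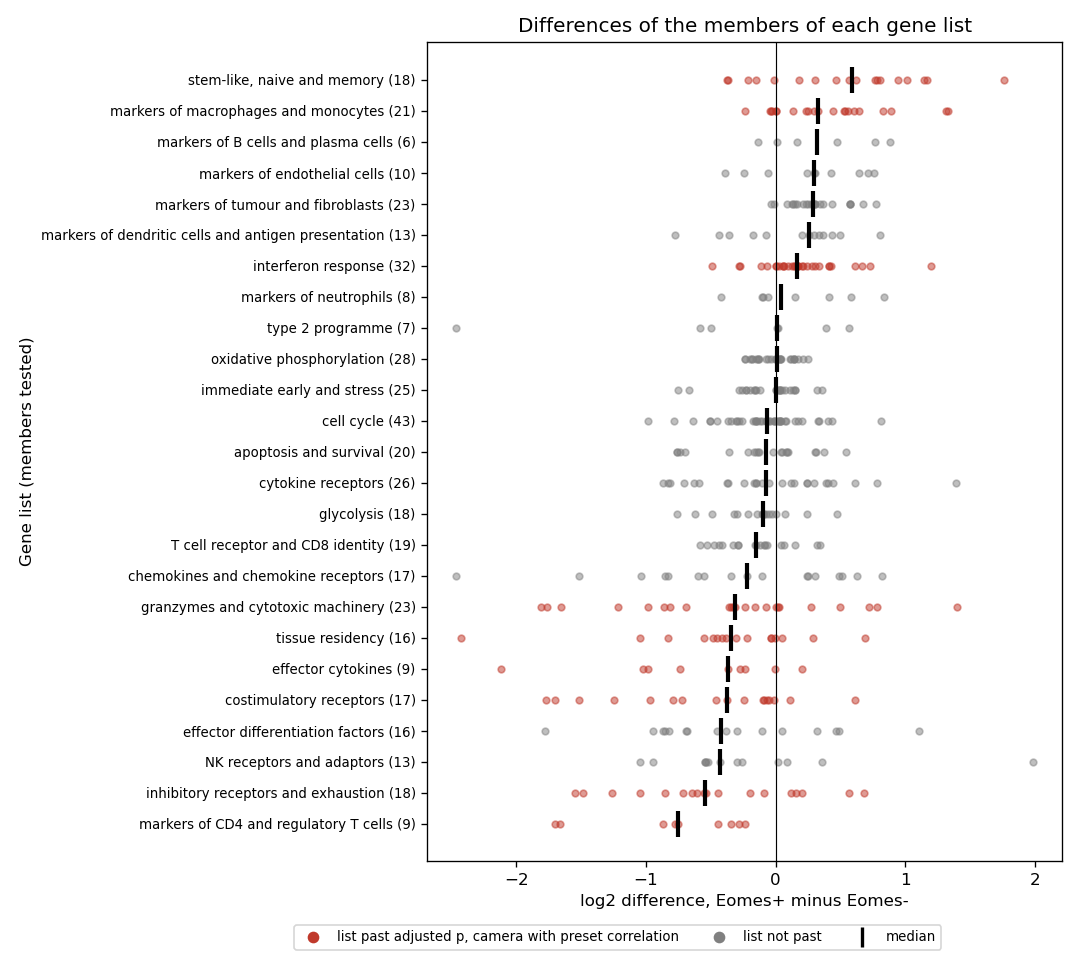
Log2 difference, Eomes+ minus Eomes- (horizontal axis), of each tested member (points) of 25 gene lists (vertical axis, members tested in brackets), with the list median as a black bar and red for lists past an adjusted p of 0.05 in camera with the preset correlation. List medians run from -0.75 for CD4 and regulatory T cell markers to 0.59 for stem-like, naive and memory genes.

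In all, 9 of 25 tested lists passed camera with the preset correlation, 3 higher and 6 lower, whereas 0 passed with an estimated correlation and 0 passed limma's fry. Effector differentiation factors had a median of -0.42 log2 (adjusted p = 0.0517), with Irf4 at -1.78 log2 (SE 0.58), Bhlhe40 at -0.69 (SE 0.25), Tbx21, which encodes T-bet, at -0.38 (SE 0.59), Klrg1 at 0.49 (SE 0.36) and S1pr5, below the filter level on 2 of 3 Eomes- arrays, at 1.11 (SE 0.40). Cell cycle genes had a median of -0.06 log2 (43 tested, adjusted p = 0.418), with Mki67 at -0.15 (SE 0.15). Glycolysis genes had a median of -0.10 log2 (adjusted p = 0.153), with Hk1 at -0.76 (SE 0.21), whose other probe set differed in the opposite direction. T cell receptor and CD8 identity genes had a median of -0.15 log2 (adjusted p = 0.359), with Cd8a at -0.58 (SE 0.37). Medians were -0.22 log2 for chemokines and their receptors (adjusted p = 0.2), -0.43 for NK receptors and adaptors (0.279) and -0.08 for apoptosis and survival genes (0.763). In 4 lists the median, mean and test differed in sign: the type 2 programme (median 0.01, mean -0.37, test lower, adjusted p = 0.359), immediate early and stress genes (0.01, -0.07, lower, 0.568), cytokine receptors (-0.08, -0.04, higher, 0.779) and oxidative phosphorylation (0.01, -0.01, higher, 0.936). In each of these lists 0 members passed over all genes and 0 adjusted over the list alone.

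RNA of other cell types varied strongly between arrays. The mean of 23 tumour and fibroblast genes was 9.02, 10.87 and 11.66 log2 on Eomes+ arrays 1, 2 and 3, and 8.93, 9.98 and 11.72 on the Eomes- arrays. The mean of 21 macrophage and monocyte genes was 8.36, 9.91 and 10.81 against 7.93, 9.12 and 10.81, while 19 T cell receptor and CD8 identity genes lay at 11.70, 11.47 and 10.44 against 11.80, 11.79 and 10.52. Between the fractions, macrophage genes were higher in Eomes+ in 17 of 21 tested members (median 0.33 log2; camera adjusted p = 0.0447; adjusted p = 0.844 with an estimated correlation), and the direction of the test turned without Eomes+ replicate 3 or Eomes- replicate 1 (medians of -0.24 and -0.31). The call was also lost without Eomes+ replicate 2 (adjusted p = 0.198) or Eomes- replicate 2 (0.163). Without both arrays of number 1, 2 or 3 the macrophage median was 0.24, 0.17 and 0.48 log2 (camera adjusted p = 0.0114, 0.416 and 0.000607). Tumour and fibroblast genes had a median of 0.29 log2 (adjusted p = 0.0947), endothelial genes 0.30 (0.105), B and plasma cell genes 0.32 (0.0719), dendritic cell and antigen presentation genes 0.26 (0.418) and neutrophil genes 0.04 (0.574). Lists of gamma-delta T and NK cells (1 tested member) and red blood cells (3) were too small to test. Over these marker lists 0 members passed over all genes and 0 adjusted over the list alone.

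**Figure D3:**
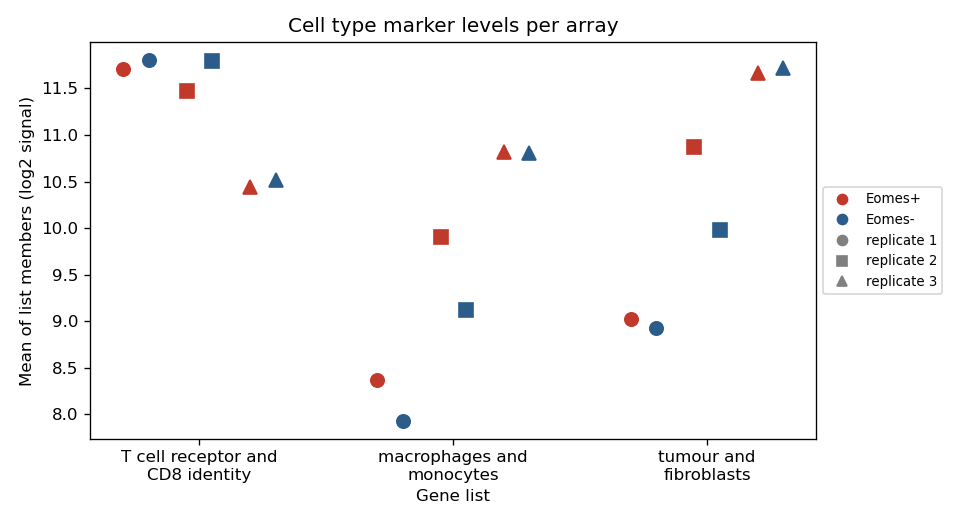
Mean log2 signal (vertical axis) of the tested members of 3 cell type lists (horizontal axis) on each of the 6 arrays, with colour for the fraction and marker shape for the replicate number. Tumour and fibroblast genes lay at 11.66 and 11.72 on the arrays of replicate 3 and at 9.02 and 8.93 on those of replicate 1.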

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

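The covariate for other cells' RNA and the block combined with other choices were chosen after seeing the data. Over all alternatives, named genes kept direction and side of the threshold in 1282 values, newly passed in 80 and turned in 10, while lists did so in 534, newly passed in 60, lost the call in 51 and turned in 51. The cause was not tested. Signals near background limit what can be said of dim genes.

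Replicate numbers shared by the fractions did not meet the rule for pairing: over all probe sets the deviations of same-numbered arrays correlated at 0.595, 0.0989 and 0.628, and Eomes- replicate 2 correlated better with Eomes+ replicate 1 (0.302). Over 18 spiked-in control probe sets the same-numbered arrays correlated at 0.977, 0.986 and 0.774, each array best with its own number, a hint from the data and not the design. The calls of both fits were already known when this check was made. With the replicate block limma called 17 genes (6 higher, 11 lower) against 0 without it, 212 uncorrected 2-fold genes against 122, and Eomes at 3.15 log2 (adjusted p = 0.0167), and 14 lists against 9 (0 with an estimated correlation, 0 with fry). The block gave 1276 genes at an unadjusted p under 0.05 against 409 without it, where chance alone gives 629. Lists added by the block were effector differentiation factors (camera adjusted p = 0.00105), NK receptors (0.00176), T cell identity (0.00176), glycolysis (0.0161) and tumour and fibroblast genes (2.23e-05). Of the inhibitory receptor list, 11 members then fell when adjusted over the list alone, and Lag3 over all genes. The block left 306 uncorrected genes without replicate 1, 252 without replicate 2 and 402 without replicate 3, and called 0, 0 and 111 genes in that order, with 16 lists without replicate 3. The Eomes log2 difference stayed at 2.97, 3.24 and 3.25, and fewer arrays were left for the fit, so lost calls do not show smaller differences.

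Array weights gave 253 genes, 727 uncorrected genes, 14 lists and Eomes at 2.93 log2 (adjusted p = 0.0273). Of the 253 genes, 12 were among the 17. The covariate for other cells gave 8 genes, all 8 among the 17, 203 uncorrected genes and Eomes at 3.37 log2 (adjusted p = 0.0294), and 0 lists with an estimated correlation. Uncorrected genes were 60 with a pseudocount of 64, 73 with the stricter filter and 223 over all probe sets. Lists past the threshold were 0 with an estimated correlation and 0 with fry.

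With 1 array or both arrays of a number left out, uncorrected genes ranged from 73 to 334, lists from 3 to 17, genes past the threshold from 0 to 0 and Eomes from 2.67 to 3.74 log2. The 3' to 5' ratio difference ranged from 0.24 to 0.35 log2 with 1 array left out (exact permutation p = 0.1 to 0.2). List calls were also lost for granzymes without probe sets open to cross-hybridisation (adjusted p = 0.0814) and with the covariate (0.0628), for cytokines without a filter (0.0519) and with the covariate (0.0596), and for macrophage markers with quantile normalization (0.0599), without a filter (0.0984) and with the covariate (0.627).

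A sign also turned in these values, of which the macrophage list alone had been past the threshold (list medians or gene differences, log2; a list turns by its test, so its median can keep its sign). With the replicate block it was cytokine receptors -0.0772. Without a filter it was cytokine receptors -0.0772, oxidative phosphorylation 0.0094 and neutrophils -0.0561. Over all probe sets it was type 2 programme 0.39. With array weights it was Gzmb -0.0812, cytokine receptors -0.13 and cell cycle 0.0841. With the covariate it was oxidative phosphorylation 0.00298, apoptosis and survival -0.0102, T cell receptor and CD8 identity 0.0237, neutrophils -0.10 and tumour and fibroblasts -0.0831. With the replicate block and without replicate 1 it was Mki67 0.00155, cytokine receptors -0.12, cell cycle 0.00233 and oxidative phosphorylation 0.00795. With the replicate block and without replicate 2 it was cytokine receptors -0.0267, oxidative phosphorylation -0.0136, neutrophils 0.061 and endothelial cells 0.0408. With the replicate block and without replicate 3 it was Gzmb -0.0199 and cytokine receptors -0.19. With fry it was cytokine receptors -0.0772 and oxidative phosphorylation 0.0094. Left-out arrays gave Gzmb (-0.31 to 0.31), cytokine receptors (-0.30 to 0.0986), cell cycle (-0.24 to 0.033), oxidative phosphorylation (-0.0237 to 0.0202), immediate early and stress (-0.15 to 0.12) and Il7r (-0.84 to 0.0698). They also gave Tbx21 (-0.92 to 0.0884), type 2 programme (-0.16 to 0.12), T cell receptor and CD8 identity (-0.51 to 0.26), macrophages and monocytes (-0.31 to 1.11), dendritic cells and antigen presentation (-0.16 to 0.64) and neutrophils (-0.39 to 0.80). Further ranges were tumour and fibroblasts (-0.36 to 1.01), endothelial cells (-0.16 to 0.93), apoptosis and survival (-0.11 to 0.0505) and Mki67 (-0.26 to 0.00155).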

Other observations

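The tests of the replicate 1 and replicate 3 difference, of list differences against other cells' RNA and of the stem-like list against RNA quality were chosen after the results were seen. Host mice were male, yet Xist, which silences the X chromosome in female cells, lay at 3.64, 7.79 and 8.45 log2 on Eomes+ arrays 1, 2 and 3 and at 3.84, 6.91 and 7.12 on the Eomes- arrays. The Y-linked genes Eif2s3y and Kdm5d were 3.48-fold and 3.38-fold lower on the arrays of replicate 3 than on those of replicate 1, where Xist lay below the 40th percentile of both arrays. Endothelial genes were higher on both arrays of replicate 3 than on those of replicate 1 in 10 of 10 tested members, by 1.52 log2 on average.

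The first principal component held 64.8% of the variance and placed the arrays of replicate 1 and replicate 3 at opposite ends, while the fractions parted on the second (12.0%). The spiked-in bioB controls did not order the arrays as the component does. They were highest on the arrays of replicate 2, in the middle of the component, by 0.655 log2 over the nearer number against at most 0.134 between arrays of 1 number. However, bioB lay at 10.79 and 10.67 log2 on the arrays of replicate 1 and at 11.18 and 11.28 on those of replicate 3. A hybridisation difference between the numbers therefore stays open. RNA from tumour cells and macrophages is a candidate source: 100% of 44 marker genes were higher on both arrays of replicate 3, tumour and fibroblast genes by 2.71 log2 on average, although the cells had been sorted as CD8 T cells. The T cell identity genes were 1.27 log2 lower there. No biological explanation was tested.

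Of the 9 lists that passed camera, the macrophage markers are part of the measure of other cells' RNA, so the test was restricted to the other 8 after a first value with all 9 was seen. With the marker level of tumour cells and macrophages as a covariate, a median share of 0.834 of the list difference was left (95% bootstrap interval over lists 0.517 to 0.944), and the ratio of the medians over lists was 0.711 (0.517 to 0.93). Intervals over lists resample lists measured on the same arrays, so they do not measure the spread between samples. The share was at least 0.8 in 5 lists and 0.386, 0.517 and 0.526 for granzymes, costimulatory receptors and tissue residency. With 1 array left out these 3 shares ranged from 0.105 to 109, -6.34 to 3.14 and 0.361 to 1.69. The interferon share ranged from 0.182 to 1.53 and the inhibitory receptor share from 0.447 to 1.17, so the share of a single list is unstable. Without Eomes+ replicate 1 both measures fell, to 0.404 and 0.457, so a part from such RNA stays open. For RNA quality, the slope on the Gapdh ratio within groups gave a median of -1.25 of the differences (interval over lists -2.63 to 0.2), against their direction in 7 of 9 lists. With each array left out the median lay between -1.97 and -0.378. In both fractions the ratio was highest on replicate 1, where the tumour and macrophage markers were lowest. The slope therefore mixes RNA quality with other cells' RNA, and it cannot decide on RNA quality. The slope ran with the difference for the CD4 and regulatory T cell markers (0.2) and for the stem-like, naive and memory list (1.63, and 0.675 to 5.24 with each array left out). For the stem-like list it gave 0.966 log2, near the 0.976 for costimulatory receptors, which were lower in Eomes+. The share of 1.63 therefore does not single out RNA quality. For this list RNA quality and a difference between Eomes+ and Eomes- cells both stay open.

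CD4 T cells in the Eomes- fraction are a possible explanation for the lower CD4 and regulatory T cell markers, which the sort on CD8 would be meant to remove. Cd4 differed by -0.236 log2 (95% interval -0.896 to 0.424) and Foxp3 by -0.34, against a list median of -0.75. The interval for Cd4 holds both 0 and the list median, so this explanation and a difference in CD8 T cells cannot be told apart. Cd4 lay at 7.32 log2 on the Eomes- arrays and Cd8a at 13.20, but signals of different probe sets do not give the relative amounts of their RNA.

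The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past an adjusted p of 0.05 and the highest other 980. Against a count of 0 all 10 splits give at least as many whatever the data, so that comparison is void. For the uncorrected 2-fold genes 5 of 10 splits gave at least the real 122, up to 1684, and for gene lists 5 of 10 gave at least the real 9, up to 17. Besides the real split, those that set apart the arrays of every number gave 45, 25 and 27 genes and 4, 1 and 0 lists. Such splits are too few for a test. The other 4 splits at or above the real values each held both arrays of 1 number on one side, and the split with 980 genes set both arrays of replicate 1 and Eomes- replicate 2 against the others, which points to a structure of the samples other than their fraction.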
